A study of Mus musculus with 26 samples.

How the data were processed

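Total RNA was extracted with Trizol from frozen mouse cortex holding the stroke and the tissue around it, or from sham cortex, and sequenced as stranded paired-end total RNA libraries on an Illumina instrument, per the labels' protocols. Per the submitters' processing notes, the tools named are Trim Galore, STAR, featureCounts and HTSeq and the build is mm9, with no role, order, version or annotation given. The deposited values are whole-number counts per Ensembl gene, 1 table per library, and the authors applied no normalization to them as far as the values show. Each table held 39179 gene entries and 5 summary entries (fragments outside genes, ambiguous, low quality and not uniquely placed). The summary entries held between 45.69% and 58.16% of all counts in a file and were left out of library sizes and tests. The gene identifiers are later than those usual with mm9, so no coordinates are printed. Names came from a GENCODE M21 table that matched 37607 identifiers.

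The 26 libraries fall into 6 groups by operation, diet and weeks. Nothing in the labels says that each library comes from a separate animal, so the p-values measure the spread between these libraries. Pairs of libraries within a group differed by 3.52 to 76.2 times the chi-square expected from counting alone, so no pair is the same library counted again, which does not exclude that libraries share an animal.

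Genes passed filterByExpr in edgeR 4.0.16 with a minimum count of 10, which left 16325. Counts were scaled by TMM and fitted over all 26 libraries with 1 mean per group by edgeR's quasi-likelihood method (robust, R 4.3.3), and 9 contrasts were tested with Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change is its size divided by the square root of the test's F, and CPM values are scaled by TMM. The common dispersion was 0.0184, a biological coefficient of variation of 0.136. The 39 gene lists cover 31 processes or cell types and 8 other tissues, with 572 of 623 members tested. They were tested with camera in limma 3.58.1 (preset correlation of 0.01, and again with an estimated correlation) and with fry. List levels per library, the mean log2 CPM with a prior count of 2, were compared by exact two-sided permutation tests, and 0 of 273 passed adjustment over that family. Group sizes limit these tests, since the smallest possible p was 0.0286 and 0.0119 for stroke against sham on the control and high-fat diet. For diet in sham it was 0.1. Cell cycle genes, whose list means did not overlap between stroke and sham, thus had an adjusted p of 0.153 and 0.13. The 0 is therefore no sign that the lists are unchanged. Meninges, hypothalamus and hypoxia lists were called in no comparison by camera.

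Genes named in the text follow a rule: up to 8 called genes per direction with the largest change, a name that is not a predicted or clone name, a mean CPM of at least 5 in the higher group and no overlap between groups, up to 4 members per described list with the smallest p, and, where fewer than 16 genes were called, the 5 smallest p. Groups, contrasts, tests, lists, this rule and the alternatives listed next were fixed before the data were examined. Alternatives were RLE size factors, DESeq2 1.42.0, no filter and a stricter filter, only the groups compared, a non-robust fit, voom with quality weights, removal of mitochondrial, ribosomal RNA and haemoglobin genes, 1 surrogate variable (sva 3.50.0), the excitatory neuron list mean as a covariate and leaving out each library. The share of fragments outside genes as a covariate, the sets of libraries left out together and the Gm10800-like genes were chosen after seeing the data. Those 13 genes have a transcript matching the longest Gm10800 transcript at 80% identity or more over at least 100 bases, so fragments may be shared between them and their counts are uncertain one by one.

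The fit was tested on simulated counts drawn from mean levels and dispersions of the real data with 200 genes changed by known folds in the first group of each comparison, and between 3.21% and 8.72% of its calls were false. Of genes changed 2-fold, it recovered 71.6% for stroke against sham on the control diet, 86.6% on the high-fat diet, 68.7% for surgery by diet, 77.6%, 83.6% and 73.1% for diet in 6-week stroke, 15-week stroke and sham, 76.1% for diet by weeks, and 74.6% and 80.6% for weeks on the control and high-fat diet. Of genes changed 1.5-fold it recovered between 40.3% and 61.2% over these comparisons. The simulation drew genes independently, with 1 dispersion per gene for all groups, while the real spread differed between groups. The activated phagocyte list mean had an SD of 0.95 and 0.74 log2 CPM in 15-week high-fat and control stroke. At 6 weeks the SDs were 0.25 and 0.55. Recovery may thus be overstated for injury genes, most of all at 15 weeks. Genes near the filter are measured by about 10 counts, so small changes of low genes are not detectable at the depth of these libraries.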

Results

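RNA of mouse cortex was sequenced 3 days after an experimental stroke or a sham operation in mice kept on a diet with 60% or 6% of its calories from fat. C57BL/6J is a common inbred strain that becomes obese on a high-fat diet. No strain or body weight entered the comparisons, so obesity of these mice was not tested. The 6-week arm held 6 stroke libraries on the high-fat diet, 4 stroke libraries on the control diet and 3 sham libraries on each diet. The 15-week arm held 6 stroke libraries on the high-fat diet and 4 on the control diet, and a 15-week sham group was not analysed here. Each of the 26 libraries had between 11400882 and 16962682 counts in genes, and 16325 genes were tested. The first principal component held 58.11% of the variance between libraries. The comparisons address how stroke, the diet and the time on the diet change gene expression in injured cortex. The labels give no age or batch. Comparisons of 15 with 6 weeks thus cannot tell time on the diet from the age of the mice or from separate handling.

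On the control diet, stroke was followed by higher levels of genes of activated phagocytes, reactive astrocytes, dividing cells and the interferon response. The osteopontin gene Spp1, made by phagocytes in injured tissue, stood at 393 ± 248 CPM (SD, n = 4) after stroke and at 12.4 ± 3.16 CPM (SD, n = 3) after sham surgery. Its log2 fold change was 4.99 ± 0.97 (SE, adjusted p = 0.00588). Gfap, the intermediate filament gene of astrocytes, went from 97.3 ± 10.2 CPM in sham to 693 ± 161 CPM in stroke. The macrophage survival factor Cd5l was at 7.60 ± 4.99 CPM after stroke and at 0.0461 ± 0.0799 CPM after sham surgery. The neutrophil and astrocyte gene Lcn2 was at 6.30 ± 2.13 and 0.274 ± 0.303 CPM. Tgm1, Lgals3, Msr1, Zbp1 and Clec7a were the other genes with the largest rises under the naming rule, with log2 fold changes of 6.76, 4.73, 4.54, 4.74 and 4.45. The lipid droplet coat gene Plin4 fell by 2.11 ± 0.38 on the log2 scale (SE, adjusted p = 0.00353), from 16.4 ± 6.91 to 3.77 ± 0.919 CPM. Etnppl, Wnt10a, Etnk2, Ppp1r3g, Alox12b, Tsc22d3 and Tspan11 followed among the genes that fell, with log2 fold changes between -1.38 and -0.85.

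Counted by gene list, 17 of 20 cell cycle genes rose on the control diet, among them Mki67 (log2 4.15 ± 0.65), Cdk1 (4.16 ± 0.67) and Top2a (3.79 ± 0.63). In this list 19 rose adjusted over the list alone. Of 22 type I interferon response genes, 18 rose, 21 adjusted over the list alone, with Mx1 at a log2 fold change of 3.22 ± 0.62 and Oas2 at 3.43 ± 0.73. Activated phagocyte genes rose in 15 of 20 cases, 17 adjusted over the list alone. Reactive astrocyte genes rose in 14 of 21 cases, 19 adjusted over the list alone, including Vim (3.02 ± 0.59) and Serpina3n (3.22 ± 0.70). Homeostatic microglia genes, which are often described as lower in activated microglia, rose in 10 of 12 cases (12 adjusted over the list alone), with Olfml3 at 2.05 ± 0.36 and P2ry12 at 0.78 ± 0.12. Antigen presentation genes rose in 11 of 19 cases and complement genes in 6 of 14, or 16 and 9 adjusted over the list alone. Cytokines and chemokines rose in 12 of 20 cases and monocyte genes in 9 of 17, or 17 and 15 adjusted over the list alone. The glucocorticoid response list went the other way, since 8 of its 16 tested genes fell and none rose, with Tsc22d3 at -0.89 ± 0.12 and Ddit4 at -0.49 ± 0.11. Adjusted over the list alone, 9 fell and 1 rose. Of 24 oxidative phosphorylation genes, 3 fell (3 adjusted over the list alone), by 0.24 (Ndufb8), 0.20 (Atp5a1) and 0.21 (Ndufv1) on the log2 scale. Mitochondrially encoded genes held 8.40 ± 0.205% of counts in stroke (SD, n = 4) and 7.66 ± 0.477% in sham (SD, n = 3, two-sided exact p = 0.0286, the smallest possible, adjusted p = 0.178), and the share of fragments outside genes was 29.7 ± 2.74% and 34.2 ± 1.32% (two-sided exact p = 0.0571). None of 20 excitatory neuron genes passed, over all genes or adjusted over the list alone. The list mean was 7.78 ± 0.09 log2 CPM in stroke (SD, n = 4) and 7.93 ± 0.05 in sham (SD, n = 3).

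In all, edgeR called 1253 genes on the control diet, 833 higher and 420 lower. Of these, 574 of the higher and 18 of the lower genes changed at least 2-fold. Camera called 22 of the 39 gene lists with its preset correlation, and no camera call in any of the 9 comparisons held with an estimated one. For the cell cycle, interferon, phagocyte, astrocyte, microglia, monocyte, cytokine and glucocorticoid lists the adjusted p = 0.125 with an estimated correlation, for antigen presentation and complement the adjusted p = 0.192 with an estimated correlation. For oxidative phosphorylation the adjusted p = 0.526 with an estimated correlation and for excitatory neurons the adjusted p = 0.551 with an estimated correlation. In contrast fry, which asks whether a list's genes move on balance one way, called 17. The gene count was 303, 324 and 465 without sham replicates 1, 2 and 3, and 345 and 623 without stroke replicates 2 and 3. It was 767 with no filter on low counts, 533 with the share of fragments outside genes as a covariate, 2453 with only the groups compared, 2666 with a surrogate variable and 2860 by voom.

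On the high-fat diet, genes of the same lists were higher after stroke. Spp1 stood at 682 ± 207 CPM (SD, n = 6) after stroke against 12.2 ± 3.02 CPM (SD, n = 3) after sham surgery, Gfap at 864 ± 51.4 against 91.0 ± 5.10 CPM, and Tgm1, a crosslinking enzyme, at 26.2 ± 5.92 against 0.0472 ± 0.0817 CPM. Cd5l and Lcn2 had no count in any of the 3 sham libraries and stood at 14.7 ± 4.87 and 8.45 ± 3.10 CPM after stroke. The chemokine genes Cxcl10 and Ccl2 and the myeloid gene Slfn4 rose from 0.0472 ± 0.0409, 0.0720 ± 0.125 and 0.0473 ± 0.0819 CPM to 7.78 ± 2.36, 5.60 ± 1.46 and 5.54 ± 4.80 CPM. Slfn4 was at 15.1 CPM in stroke replicate 5 and at 2.13 to 4.95 CPM in the other 5. Lgals3 and the interferon-induced gene Ifi209 rose by 6.32 ± 1.17 and 6.28 ± 0.95 on the log2 scale (SE, adjusted p = 0.000878 and 0.000282). The genes that fell most under the naming rule were Cbln4 (-1.19 ± 0.21), Etnppl (-1.05 ± 0.24), Alox12b (-0.98 ± 0.23), Ppp1r3g, Tmem200b, Col24a1, Tspan11 and Dmp1.

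All 20 cell cycle genes, all 19 antigen presentation genes and all 12 homeostatic microglia genes rose on the high-fat diet, and the same numbers rose adjusted over the list alone. Interferon response genes rose in 21 of 22 cases, reactive astrocyte genes in 19 of 21, activated phagocyte genes in 17 of 20, and monocyte genes in 16 of 17, or 22, 20, 19 and 16 adjusted over the list alone. Extracellular matrix and fibroblast genes rose in 16 of 20 cases (17 adjusted over the list alone), with Mmp14 at 1.92 ± 0.34, Tgfbi at 3.62 ± 0.76 and Tnc at 3.59 ± 0.76. Cytokines and chemokines rose in 16 of 20 cases (18 adjusted over the list alone). Genes of lipid handling also rose. Of these, 12 of 22 fatty acid oxidation and PPAR target genes were called higher and 1, Plin4, lower (14 and 1 adjusted over the list alone), with Plin2 at 3.86 ± 0.73 and the fatty acid transporter Cd36 at 3.31 ± 0.64. Of 15 cholesterol efflux and lipid droplet genes, 8 rose, with Npc2 at 1.15 ± 0.25 and Nr1h3 at 0.96 ± 0.23 (adjusted over the list alone, 9 rose and 1 fell). Activated endothelium genes rose in 10 of 16 cases, oligodendrocyte precursor genes in 7 of 11, endothelium and barrier genes in 7 of 16 and complement genes in 10 of 14, or 11, 8, 9 and 11 adjusted over the list alone. Excitatory neuron genes fell in 7 of 20 cases, 10 adjusted over the list alone, with Camk2a at -0.54 ± 0.16, Grin2a at -0.46 ± 0.12 and Snap25 at -0.40 ± 0.13. Their list mean was 7.76 ± 0.06 log2 CPM in stroke (SD, n = 6) and 8.03 ± 0.15 in sham (SD, n = 3), where replicate 2 stood at 8.20. Circadian clock genes fell in 6 of 16 cases (6 adjusted over the list alone), with Arntl at -0.46 ± 0.10. Haemoglobin and other blood cell genes rose in 5 of 6 cases (5 adjusted over the list alone), with Hba-a2 at 1.26 ± 0.22. Their list mean was 5.04 ± 0.28 log2 CPM in stroke and 4.13 ± 0.34 in sham, where replicate 2 stood at 3.74. On the control diet the excitatory neuron and blood cell lists stood at 7.78 and 5.03 in stroke and at 7.93 and 4.69 in sham. For these lists the diets thus lay closer in stroke than in sham. Among markers of other tissue the choroid plexus list mean was 4.51 log2 CPM in high-fat stroke replicate 6 against at most 1.18 in the other 5. In high-fat sham replicate 2 it was 3.08. On the control diet the list means of matrix, PPAR target, cholesterol efflux and activated endothelium genes were also higher in stroke. They were 3.54, 3.56, 3.98 and 2.27 log2 CPM in stroke (n = 4) against 2.05, 3.21, 3.42 and 1.33 in sham (n = 3). By the exact test the adjusted p was 0.226 for matrix and PPAR targets and 0.153 for the others.

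On the high-fat diet 3769 genes were called, 2324 higher and 1445 lower, with at least 2-fold changes in 1235 and 41 of them. Camera called 25 lists and fry 27. For the cell cycle, antigen presentation, microglia, interferon, astrocyte, phagocyte and cytokine lists the adjusted p = 0.126 with an estimated correlation, and for the excitatory neuron and circadian lists the adjusted p = 0.345 with an estimated correlation. For the matrix, blood cell and activated endothelium lists the adjusted p = 0.155 with an estimated correlation, for monocytes and complement the adjusted p = 0.134 with an estimated correlation and for PPAR targets the adjusted p = 0.16 with an estimated correlation. The count was 1991 without sham replicate 2, 1833 without both libraries high in choroid plexus genes, 1342 with the share of fragments outside genes as a covariate and 5834 by voom. That share was 30.4 ± 1.29% in stroke (SD, n = 6) and 36.4 ± 1.99% in sham (SD, n = 3, two-sided exact p = 0.0119, the smallest possible, adjusted p = 0.167).

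**Figure D1:**
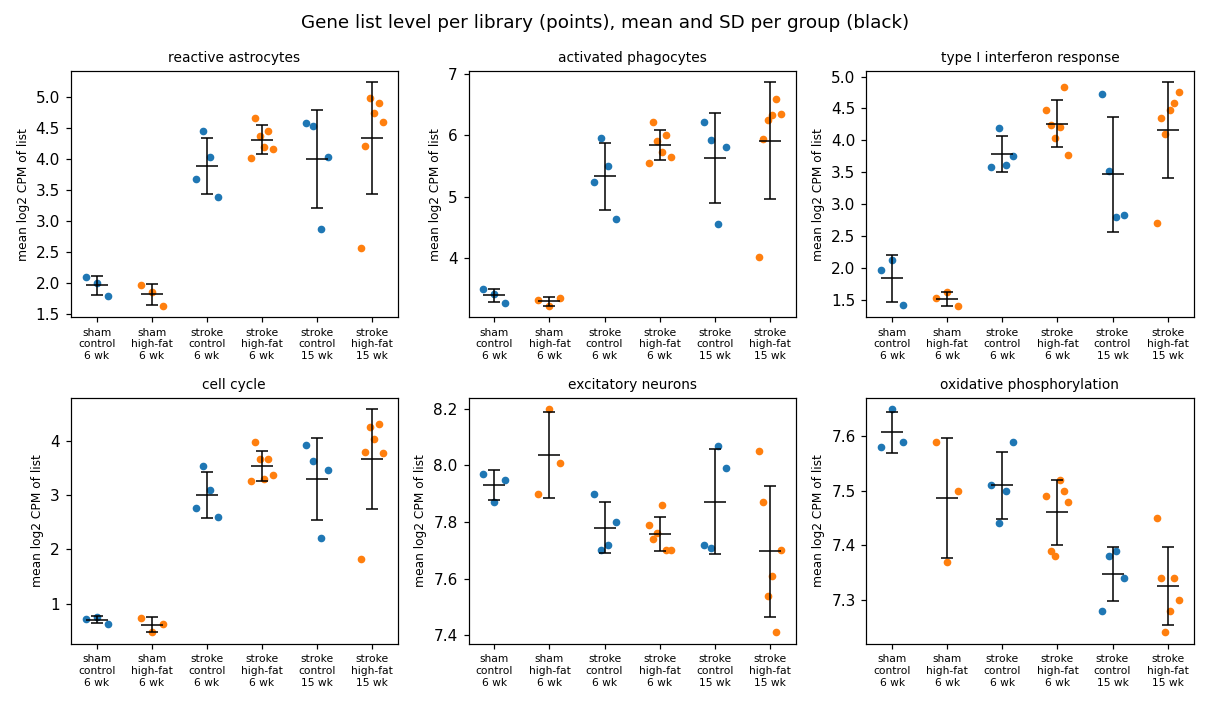
Each point is 1 library and gives the mean log2 CPM of the genes of a list (vertical axis) by group (horizontal axis), with the group mean and SD in black, control diet in blue and high-fat diet in orange. Reactive astrocyte genes lay at 1.96 ± 0.15 in control sham and 3.88 ± 0.45 in control stroke, and stroke high-fat 15-week replicate 1 sits at 2.57, apart from its group.

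The fold changes of both stroke comparisons, which share no library, ran together across genes (Pearson r = 0.879 over 16325 genes, which are not independent replicates). Of the 833 genes called higher on the control diet, 738 were also called higher on the high-fat diet, where 118.6 would be shared by independent lists. Of the 420 called lower, 219 were shared against 37.18. The test of the difference itself, surgery by diet, called 0 genes in edgeR (914 at unadjusted p under 0.05, where 816 are expected with no effect). DESeq2 and voom each called 1 gene, Junb in both (adjusted p = 0.0101 in DESeq2 and 0.00315 in voom), with 986 and 2333 genes at unadjusted p under 0.05. Junb, an immediate early transcription factor gene, had a log2 difference of 1.28 ± 0.25 (SE, adjusted p = 0.509 in edgeR), from 76.0 ± 12.1 to 52.6 ± 9.06 CPM on the control diet and from 39.1 ± 11.1 to 65.8 ± 7.66 CPM on the high-fat diet. Ier5l, Gpr62, Slc16a1 and Adam21 had the next smallest p values, with log2 differences of 1.16, 0.79, 0.55 and 1.96 and adjusted p of 0.715, 0.715, 0.715 and 0.826. Among the lists, interferon response genes had a median log2 difference of 0.88 and antigen presentation genes of 0.78. Camera called 22 lists, 18 of them upward, all with adjusted p = 0.617 or above with an estimated correlation. Glucocorticoid response and immediate early genes each had 1 member higher adjusted over the list alone, Ddit4 (0.52 ± 0.15) and Junb, and none over all genes.

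High-fat feeding on its own gave no called gene in stroke cortex at 6 weeks by edgeR, with 1141 genes at unadjusted p under 0.05. DESeq2 and voom also called 0, with 1174 and 2772. The smallest p values belonged to Hist1h2ak (log2 1.02 ± 0.23), Tcf23 (1.58 ± 0.38), Tmem263 (-0.25 ± 0.06), Gt(ROSA)26Sor (-0.45 ± 0.12) and Brcc3 (-0.24 ± 0.06), each with an adjusted p of 0.667. Extracellular matrix and fibroblast genes had a median log2 fold change of 0.61 on the high-fat diet, cell cycle genes of 0.48, interferon response genes of 0.51, activated phagocyte genes of 0.47 and fatty acid oxidation and PPAR target genes of 0.25. Camera called 23 lists with its preset correlation, these 5 among them, and all 5 had an adjusted p = 0.459 with an estimated correlation. With a surrogate variable camera called 8 lists, and of these 5 only the PPAR list was still called. Glucocorticoid response genes had a median of 0.19 and list means of 4.68 ± 0.07 log2 CPM on the high-fat diet (SD, n = 6) and 4.46 ± 0.09 on the control diet (SD, n = 4, two-sided exact p = 0.00476, adjusted p = 0.13), and cholesterol biosynthesis genes had a median of -0.07. For both lists the adjusted p = 0.459 with an estimated correlation. The PPAR target Angptl4, an inhibitor of lipoprotein lipase, was at 1.34 ± 0.48, with an adjusted p of 0.667. Of 15 oxidative stress genes, 1 was higher adjusted over the list alone, the ferritin gene Fth1 (0.31 ± 0.09), and none over all genes. Medians were below 0 for the striatum list (-0.64) and inhibitory neuron genes (-0.07), where the adjusted p = 0.459 with an estimated correlation for both. Only the libraries of the groups compared, fitted alone, gave 1 gene, Naip2 (log2 1.03, adjusted p = 0.0309), named after its values were seen.

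At 15 weeks the diet also gave 0 called genes in edgeR in stroke cortex (1299 at unadjusted p under 0.05). DESeq2 called 2, Sowahb and Sstr2, both lower with an adjusted p of 0.0468 and 0.0245 (1366 at unadjusted p under 0.05), and voom 0 (1715). On each diet 1 library lay between sham and the other stroke libraries, high-fat replicate 1 and control replicate 3. Their injury scores were low, at 0.375 and 0.482, where 0 is the mean of sham and 1 that of 6-week stroke. The highest sham score was 0.032 and the lowest 6-week stroke score 0.693. Camera called 24 lists with its preset correlation, and 10 without control replicate 3. The lists named in this paragraph kept the preset-correlation call with each of the 10 libraries left out. The somatostatin receptor gene Sstr2 was at a log2 fold change of -0.54 ± 0.10, Sowahb at -0.56 ± 0.12, the prohormone convertase gene Pcsk1 at -0.45 ± 0.10, the interneuron peptide gene Vip at -0.35 ± 0.08 and B3galt5 at 0.48 ± 0.11, all with an adjusted p of 0.257. The excitatory neuron list had a median of -0.14 with no member lower over all genes or adjusted over the list alone, and list means of 7.70 ± 0.23 and 7.87 ± 0.19 log2 CPM on the high-fat and control diet (adjusted p = 0.385 with an estimated correlation). Immediate early genes, which are induced by neuronal activity, had a median of -0.55, and 6 of 13 were lower adjusted over the list alone, among them Nr4a1 (-0.74 ± 0.21), Egr1 (-0.73 ± 0.22) and Arc (-0.77 ± 0.24). Circadian clock genes had a median of -0.20 with 3 of 16 lower adjusted over the list alone, including Bhlhe40 (-0.46 ± 0.12). For both lists the adjusted p = 0.316 with an estimated correlation. Immediate early list means were 4.31 and 4.76 log2 CPM on the high-fat and control diet, against 4.36 and 4.18 at 6 weeks. Circadian list means were 5.55 and 5.78, against 5.52 and 5.59 at 6 weeks. On both lists the 15-week control group was thus the highest of the stroke groups. Interferon response genes had a median of 0.59 and myelin genes of 0.21 (adjusted p = 0.385 with an estimated correlation for both). The interferon list mean was 2.71 log2 CPM in high-fat replicate 1 against 4.10 to 4.75 in the other 5. In the control libraries it was 4.72, 3.52, 2.80 and 2.83 (two-sided exact p = 0.21 for the difference between diets). Plin4 was at 1.15 ± 0.36 with an adjusted p of 0.471, and high-fat replicate 6 stood apart from its group at 12 CPM. Ciliated ependymal genes, markers of the ventricle lining, had a median of 0.36 with 1 of 9, Tmem212 (2.03 ± 0.50), higher adjusted over the list alone (adjusted p = 0.316 with an estimated correlation). Striatum genes had a median of 0.88 (adjusted p = 0.433 with an estimated correlation). Leaving out stroke high-fat replicate 1 gave 1 called gene, St6galnac6 (-0.34, adjusted p = 0.0165). Leaving out replicate 2 gave Sstr2 (-0.61, adjusted p = 0.0449), the former named after its values were seen.

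In sham cortex the diet gave 0 called genes by edgeR at 6 weeks (782 at unadjusted p under 0.05), while DESeq2 and voom each called Junb (819 and 2041 at unadjusted p under 0.05). Its adjusted p was 0.0452 in DESeq2 and 0.00232 in voom. Junb was at a log2 fold change of -0.96 ± 0.20 (adjusted p = 0.781 in edgeR), the transferrin receptor gene Tfrc at -0.35 ± 0.08, Sertad1 at -0.88 ± 0.20, Ubap2 at 0.36 ± 0.09 and Fis1 at -0.25 ± 0.06. Oxidative phosphorylation genes had a median of -0.13 (adjusted p = 0.694 with an estimated correlation), and no member was lower over all genes or adjusted over the list alone. Blood cell genes had a median of -0.61, with 1 of 6, Hba-a2 (-0.72 ± 0.24), lower adjusted over the list alone (adjusted p = 0.362 with an estimated correlation). The choroid plexus list mean was 1.52 ± 1.44 log2 CPM in high-fat sham (SD, n = 3) and 0.62 ± 0.77 in control sham, where 3 against 3 libraries allow no exact p below 0.1.

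Diet fold changes at 6 and 15 weeks in stroke cortex had a Pearson r of 0.274 across genes, and those in sham and stroke at 6 weeks one of -0.056. Without stroke control 15-week replicate 3 the former was 0.054, and without sham control replicate 1 the latter was 0.014. The diet by weeks test called 0 genes in edgeR, DESeq2 and voom (792, 878 and 1106 at unadjusted p under 0.05). The smallest p values belonged to Adra1d (log2 -0.83 ± 0.18), Ap1s2 (0.63 ± 0.14), Fezf2 (-0.58 ± 0.15), Ier5l (-0.88 ± 0.23) and Cep70 (0.45 ± 0.12), each with an adjusted p of 0.946. Immediate early genes had a median log2 difference of -0.66, and 3 of 13, including Egr4 (-1.08 ± 0.29) and Junb (-0.75 ± 0.22), were lower adjusted over the list alone (adjusted p = 0.321 with an estimated correlation). Markers of striatum, a region beneath the cortex, had a median difference of 1.52 (adjusted p = 0.499 with an estimated correlation), since their list mean was 5.58 ± 0.52 and 4.26 ± 0.63 log2 CPM at 6 and 15 weeks on the control diet and 4.79 ± 0.86 and 5 ± 1.11 on the high-fat diet.

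Between 6 and 15 weeks on the control diet, 39 genes rose and 53 fell in stroke cortex. Klf4 rose by 1.06 ± 0.18 on the log2 scale (SE, adjusted p = 0.0357), Junb by 0.74 ± 0.17, the collagen gene Col6a2 by 0.74 ± 0.16 and Igfbp5 by 0.64 ± 0.12. Vaultrc5, a small vault RNA, went from 1.37 ± 0.428 to 5.39 ± 1.03 CPM (log2 1.99 ± 0.45, adjusted p = 0.0448). Sned1, Grm2 and Hdac7 also rose, and Ttc30a1 (-0.57 ± 0.13), Otub2, Ap1s2, Vstm2b, Eef1akmt1, Fpgt, Med29 and Mrps24 fell. Of 24 oxidative phosphorylation genes, 2 fell, Cox7a2 (-0.36 ± 0.07) and Atp5o (-0.25 ± 0.06), and 13 fell adjusted over the list alone (adjusted p = 0.528 with an estimated correlation). Of 13 immediate early genes 1, Junb, rose and 5 rose adjusted over the list alone (adjusted p = 0.528 with an estimated correlation). Extracellular matrix genes had a median of 1.01 with 3 of 20 higher adjusted over the list alone, Col5a1 (0.87 ± 0.24) among them. Striatum genes had a median of -1.30 with 8 of 11 lower adjusted over the list alone (adjusted p = 0.567 with an estimated correlation for both). Blood cell genes had a median of -0.55, with 4 of 6 lower adjusted over the list alone (adjusted p = 0.528 with an estimated correlation). The share of counts in mitochondrially encoded genes was 9.12 ± 0.692% at 15 weeks and 8.40 ± 0.205% at 6 weeks (SD, n = 4 each, two-sided exact p = 0.114), and that of Gm42418 0.188 ± 0.152% and 0.0568 ± 0.0230% (two-sided exact p = 0.0286, adjusted p = 0.178). The 15-week mean includes replicate 3 at 0.413%. In all 92 genes were called. The count was 0 without 6-week replicate 2, 3 or 4 or 15-week replicate 1, 59 without 6-week replicate 1, 19 without 15-week replicate 3, and 3 without 15-week replicate 4 (Klf4, Aplp1 and Atp5k, named after their values were seen). It was also 0 with no filter on low counts, with only the groups compared, or with the share of fragments outside genes as a covariate. It was 17 with a surrogate variable and 44 with RLE size factors, against 247 by DESeq2 and 329 by voom. With the excitatory neuron list mean as a covariate it was 680, and without both 15-week libraries with low injury scores 514. The share of fragments outside genes was 35.4 ± 2.91% at 15 weeks and 29.7 ± 2.74% at 6 weeks (SD, n = 4 each, exact p = 0.0571).

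Between 6 and 15 weeks on the high-fat diet, 120 genes rose and 264 fell. The small nuclear RNA Rnu12 went from 11.2 ± 8.89 CPM (SD, n = 6) at 6 weeks to 51.6 ± 21.7 CPM (SD, n = 6) at 15 weeks (log2 2.22 ± 0.54, adjusted p = 0.0350) and Rnu11 from 2.50 ± 0.833 to 7.10 ± 2.22 CPM (1.51 ± 0.25, adjusted p = 0.0044). The Notch ligand gene Jag1 (0.68 ± 0.17), Spaca6, Gfpt2, Safb2, the long noncoding RNA Meg3 and Hnrnpa1 also rose. The gastrin-releasing peptide gene Grp fell by 0.88 ± 0.17, cortistatin (Cort) by 0.78 ± 0.14, Lmo1 by 0.73 ± 0.17, Galnt9 by 0.59 ± 0.07 (adjusted p = 0.000169) and the prostaglandin D synthase gene Ptgds by 0.59 ± 0.15, followed by Fbxl15, Rprml and Abhd8. Oxidative phosphorylation genes fell in 5 of 24 cases, led by Ndufv1 (-0.24 ± 0.05) and Ndufa9 (-0.21 ± 0.04), and in 12 adjusted over the list alone (adjusted p = 0.944 with an estimated correlation, fry adjusted p = 0.0471). Homeostatic astrocyte genes fell in 3 of 16 cases, Aldoc (-0.33 ± 0.06), Acsbg1 (-0.26 ± 0.06) and Gjb6 (-0.25 ± 0.06), and in 4 adjusted over the list alone (adjusted p = 0.944 with an estimated correlation, fry adjusted p = 0.0471). All members of the oxidative phosphorylation list are encoded in the nucleus, while mitochondrially encoded genes held 9.74 ± 0.993% of counts at 15 weeks and 8.15 ± 1.02% at 6 weeks (SD, n = 6 each, two-sided exact p = 0.026, adjusted p = 0.178). Gm42418 held 0.616 ± 0.722% and 0.0941 ± 0.0638% (two-sided exact p = 0.0671). At 15 weeks replicates 1 and 6 held 1.75% and 1.29% and the other 4 at most 0.330%, and at 6 weeks replicate 6 held 0.218%. Among single neuron genes, Neurod6 (-0.42 ± 0.07) and Vip (-0.33 ± 0.07) fell. In all 384 genes were called. In the same 6-week libraries the choroid plexus genes of replicate 6 stood apart. The count was 0 with the share of fragments outside genes as a covariate, which was 37.8 ± 4.24% at 15 weeks and 30.4 ± 1.29% at 6 weeks. It was 127 with only the groups compared, 160 with no filter, 706 by DESeq2, 1880 by voom and 702 with a surrogate variable. With the excitatory neuron list mean as a covariate it was 774, and without both 15-week libraries with low injury scores 1715. Leaving out 1 library gave between 135 and 1308 genes, with 135, 182, 190 and 187 without 6-week replicates 1, 2, 4 and 5, and 1308, 219, 145, 146 and 241 without 15-week replicates 1, 2, 3, 4 and 6.

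The time comparisons on both diets, which share no library, had a Pearson r of 0.488 across genes. Of 39 genes called higher on the control diet, 14 were also called higher on the high-fat diet, where independent lists would share 0.2867. Of 53 called lower 21 were shared against 0.8571. A difference of age or handling between the arms, shared by both diets, would give such an overlap as well. On the control diet Rnu12 had a log2 fold change of 2.46 ± 0.68 and Rnu11 one of 1.05 ± 0.31, with adjusted p of 0.0970 and 0.108. Gm10800, a predicted gene chosen after its values were seen, rose by 5.15 ± 0.99 on the control diet and by 3.03 ± 0.74 on the high-fat diet (adjusted p = 0.0357 and 0.0359). Summed over 13 genes with sequence like Gm10800, the level was 194.9 ± 207 CPM (SD, n = 10) in 15-week stroke, 12.7 ± 7.46 CPM (SD, n = 10) in 6-week stroke and 1.35 ± 0.443 CPM (SD, n = 6) in sham libraries.

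**Figure D2:**
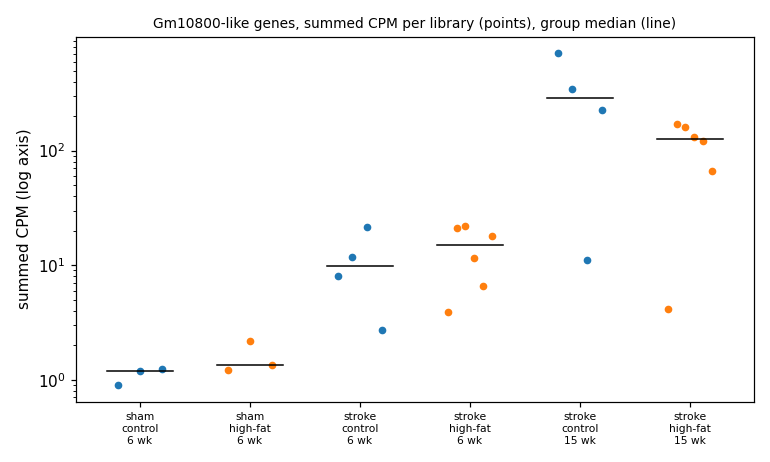
Each point is 1 library and gives the summed CPM of the 13 Gm10800-like genes on a log axis by group, with the group median as a line, control diet in blue and high-fat diet in orange. The sham libraries reach 2.20 CPM, the 6-week stroke libraries 21.9 CPM and the 15-week stroke libraries 708 CPM.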

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

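The tests of library depth and of separate batches for the Gm10800-like genes were chosen after the result was seen. So were all 3 tests of the 15-week libraries with low injury scores. The others were written before their values were known. A Dixon test was applied to 120 measures and groups, and 15 values, from 6 libraries, stood apart from their group, where chance picks about 1 in 20 groups. The sham groups, with 3 libraries each, were too small for it and were not screened. In high-fat sham, replicate 2 had a choroid plexus list mean of 3.08 log2 CPM against 0.25 and 1.22. Replicate 3 of that group had a Gm42418 share of 0.713% against 0.115% and 0.0842%. Stroke high-fat 15-week replicate 1 had a reactive astrocyte list mean of 2.57 log2 CPM against 4.2 to 4.97 in the other libraries of its group, activated phagocytes of 4.01 against 5.93 to 6.59, type I interferon response of 2.71 against 4.10 to 4.75, cell cycle of 1.83 against 3.77 to 4.30 and extracellular matrix of 2.88 against 4.57 to 5.39. Stroke high-fat 6-week replicate 6 had a choroid plexus list mean of 4.51, a Gm42418 share of 0.218% and a mitochondrial share of 10.2% against 7.51% to 8.25% in its group, replicate 5 had 15.1 CPM of Slfn4, and stroke high-fat 15-week replicate 6 had 12 CPM of Plin4. Stroke control 15-week replicate 3 had a Gm42418 share of 0.413%, 4.42 CPM of Tgm1 and 315 CPM of Gfap, and stroke control 6-week replicate 2 had 9.49 CPM of Lcn2.

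Camera with its preset correlation called 22 lists in surgery by diet, but none held with an estimated correlation (smallest adjusted p = 0.617), fry called 0 and 10 remained with 1 surrogate variable. The median log2 differences of the 22 lists were 0.92 for cytokines, 0.88 for interferon response, 0.78 for antigen presentation, 0.69 for blood cells, 0.61 for phagocytes, 0.55 for immediate early genes, 0.51 for cell cycle, 0.49 for complement, 0.46 for extracellular matrix, 0.44 for reactive astrocytes and 0.41 for ependyma. Smaller were 0.38 for activated endothelium, 0.34 for glucocorticoid response, 0.28 for myelin, 0.26 for PPAR targets, 0.23 for cholesterol efflux, 0.15 for oxidative stress and 0.08 for oxidative phosphorylation, and below 0 were striatum (-0.53), skeletal muscle (-0.35), excitatory neurons (-0.16) and circadian clock (-0.08). With at least 3 counts set as a floor in each group, the cytokine median was 0.75 and the PPAR median 0.29. In diet by weeks the medians were 1.52 for striatum, -0.66 for immediate early genes and -0.12 for excitatory neurons, and none of these 3 calls held with an estimated correlation (smallest adjusted p = 0.321) or by fry. The share of uniquely placed fragments outside genes, which were not analysed here, reached 43.1% in a 15-week stroke library and at most 37.6% in sham.

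The mean summed CPM of Gm10800-like genes was 15.34 times higher in 15-week than in 6-week stroke libraries. Apart from the 2 libraries with low injury scores, 15-week values were 226.8 to 708.2 CPM on the control and 65.99 to 171.2 CPM on the high-fat diet. In the 6-week arm they were 2.70 to 21.9 CPM in stroke and 0.899 to 2.20 CPM in sham, so these genes also differed between stroke and sham. Genomic DNA in the libraries was predicted to raise olfactory and vomeronasal receptor genes too, and the ratio of their summed CPM was 1.102. That sum was 27.3 ± 4.44 CPM in sham (SD, n = 6), 19.3 ± 3.98 in 6-week stroke and 21.3 ± 3.84 in 15-week stroke (SD, n = 10 each). It thus differed between sham and stroke and is not a fixed background, so a small amount of genomic DNA is not excluded. The ratio of count totals was 0.9167, so depth does not account for the higher Gm10800-like genes. Handling in separate batches could not be told from feeding time, and 2 of the 15-week libraries lay inside the 6-week range. These are the libraries with low injury scores described next, stroke high-fat replicate 1 with 4.111 CPM and stroke control replicate 3 with 11.02 CPM.

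For stroke high-fat 15-week replicate 1 and stroke control 15-week replicate 3, the injury scores were 0.375 and 0.482, where 0 is the mean of sham and 1 that of 6-week stroke. Sham animals under a stroke label were predicted to lie inside the sham range, and the lower score of 0.375 was above the highest sham score of 0.032 by more than the SD of 0.029. The genes of the score were chosen with these same sham libraries, all from the 6-week arm. The sham range may thus be too narrow, and a 15-week sham library could lie outside it, so a wrong label is not excluded. The lower count total was 13 M against a lowest of 12.32 M in the other 15-week stroke libraries. Depth thus does not account for the low scores. The lower excitatory neuron mean was 8.05 log2 CPM against a median of 7.71, which little injured tissue in the piece and a smaller injury would both give.

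More genes were called for stroke against sham on the high-fat diet, and this could come from 6 against 4 stroke libraries. The median over the 15 subsets of 4 high-fat stroke libraries was 2909 genes (2216 to 3921), and all 15 were above 1.5 times the control-diet count of 1253. The gap itself depended on the fit, with 3574 genes on the high-fat and 2666 on the control diet with 1 surrogate variable, and 1833 and 1328 without both libraries high in choroid plexus genes.

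Other splits of the same libraries were fitted on the compared groups only. For stroke against sham on the control diet 1 of 35 splits, the real one with 2453 genes, was as large (highest other 1072), and on the high-fat diet 1 of 84, with 3958 (highest other 3). For 15 against 6 weeks on the high-fat diet it was 1 of 100, with 127 (highest other 14). For the diet in 6-week stroke 4 of 100 splits were as large as the real 1 gene (highest other 773). Where the real count is 0 every split is as large by definition, so the splits decide nothing there, which holds for surgery by diet (40 of 40, highest other 22), diet in 15-week stroke (100 of 100, highest other 2329), diet by weeks (40 of 40, highest other 30) and 15 against 6 weeks on the control diet (35 of 35, highest other 531). Splits that call 773, 2329 or 531 genes where the real one calls 1 or 0 point to structure among the samples other than the groups, although the median over the other splits was 0 in all 3 comparisons. The sham diet comparison has only 10 splits, too few, with 0 real genes and 4 in the highest other.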

How the results depend on the processing

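No paired analysis was possible because replicate numbers were given in accession order and no pairing is named. All alternatives planned were run, the cause of a moved count was not tested, and the share of fragments outside genes as a covariate and the sets of libraries left out together were chosen after seeing the data. Stroke against sham on the control diet (1253 genes) gave 767 with no filter, 2453 with only the groups compared, 2860 by voom, 2666 with 1 surrogate variable, 533 with the outside-gene share as a covariate and 303 to 1448 leaving out 1 library. On the high-fat diet (3769) it gave 5834 by voom, 1342 with that covariate, 1833 without both libraries high in choroid plexus genes and 1991 to 3736 leaving out 1 library. Surgery by diet (0) gave 1 by DESeq2 and 1 by voom, the diet in 6-week stroke (0) 1 with only the groups compared, in 15-week stroke (0) 2 by DESeq2 and 0 to 1 leaving out 1 library, and in sham (0) 1 by DESeq2 and 1 by voom. Weeks on the control diet (92) gave 44 with RLE, 0 with no filter, 0 with only the groups compared, 247 by DESeq2 and 329 by voom. It gave 17 with 1 surrogate variable, 680 with the neuron covariate and 0 with the outside-gene covariate. Without both libraries with low injury scores it gave 514, and leaving out 1 library 0 to 133. Weeks on the high-fat diet (384) gave 160 with no filter, 127 with only the groups compared, 706 by DESeq2 and 1880 by voom. It gave 702 with 1 surrogate variable, 774 with the neuron covariate and 0 with the outside-gene covariate. Without both libraries with low injury scores it gave 1715, and leaving out 1 library 135 to 1308.

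Camera lists with an estimated correlation numbered 0 in all 9 comparisons, and fry called 0 in the interactions, the diet comparisons and weeks on the control diet, and 2 in weeks on the high-fat diet. With 1 surrogate variable camera called 10 in surgery by diet, 8 in 6-week stroke diet, 23 in diet by weeks, 19 in weeks on the control diet and 7 on the high-fat diet. On voom values it called 4 in sham diet, 17 in weeks on the control diet and 19 on the high-fat diet. Leaving out 1 library gave 20 to 22, 24 to 26, 14 to 23, 17 to 25, 10 to 26, 4 to 10, 2 to 9, 7 to 17 and 3 to 19 lists in the order of the report's comparisons (stroke on each diet, surgery by diet, diet in 6-week stroke, 15-week stroke and sham, diet by weeks, weeks on each diet). Pearson correlations of fold changes leaving out 1 library were 0.847 to 0.883 for stroke, 0.054 to 0.424 for diet at 6 and 15 weeks and 0.391 to 0.57 for weeks. For diet in sham and stroke the range was -0.102 to 0.014, with the sign reversed without sham control replicate 1. For the genes printed, 2013 alternative values kept the main status, which includes genes that were not called and stayed so. These values therefore do not tell how often a call held. Of the others, 233 lost a call, 15 gained one and 0 reversed.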
